A study of Mus musculus with 8 samples.

How the data were processed

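Gene expression was measured in multipotent progenitors from the bone marrow of female C57BL6 mice, either wild type or carrying FLT3-ITD, an internal tandem duplication in the receptor tyrosine kinase FLT3. Per the labels, the cells were lineage negative, positive for Sca-1, c-Kit and CD48, and negative for CD150. Each genotype had 4 samples, 1 array each. In each genotype 3 samples are numbered 1, 2 and 3, and the other one is also numbered 1, with the tag 037 added in brackets; it is called replicate 037 here. The meaning of 037 is not given in the sources used here, so this sample may repeat replicate 1. The 2 correlated at 0.969 in wild type and 0.953 in FLT3-ITD, the lowest correlation within each genotype. They were counted as separate samples, and averaging both was an alternative. The labels do not say whether replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical.

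Per the labels' protocols, total RNA was extracted with Trizol, amplified with a NuGEN WT-Ovation Pico kit for small RNA amounts, and labelled with biotin. The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes arrays to one distribution and summarises probes; its version is not given in the sources used here. Array medians lay between 5.98 and 6.05 and all values between 1.96 and 14.6. Scanner signal over background was not analysed here. The number of arrays limits the precision. An RMA fold understates large differences at low signal.

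The table held 45101 probe sets, of which 64 were controls. The platform annotation of 2016 gave exactly 1 gene to 34945 probe sets, several genes to 932 and no gene to 9160. For 34741 probe sets the current symbol was found through the Entrez ID in a gene table of assembly GRCm38.p6, used for names only. Each of 18193 genes was represented by its probe set with the highest mean over the 8 arrays. A gene was tested if that probe set lay above the array median on at least 4 arrays, which left 10763 genes.

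FLT3-ITD was compared with wild type using limma 3.58.1 in R 4.3.3 (linear model with empirical Bayes moderation), with no covariate. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and adjusted p-values below are limma's unless another test is named. Differences are FLT3-ITD minus wild type on the log2 scale, with standard errors from the fit. Single values were compared with exact two-sided permutation tests, which cannot give a p under 0.0286 with 4 samples against 4. Figures were drawn with matplotlib 3.10.9.

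There were 27 gene lists, 17 of pathways and progenitor programs and 10 of markers of other cell types. The 24 lists with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with adjustment over the 24 lists. Camera with an estimated correlation and fry were run beside it. The lists, the filter, the tests and the rule for named genes were fixed before the data were examined. That rule took Flt3 and the sorting markers, the 12 largest rises and 12 largest falls past the test without overlap between genotypes, and up to 4 members of each list past the test, or the 2 with the smallest p where none passed. Other genes named in the text were chosen after their values were seen.

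The procedure was tested on simulated data made from the means and spreads of the 10763 tested genes in the comparison of FLT3-ITD with wild type, with 200 genes changed. It recovered 10% of genes changed by 0.5 on the log2 scale, 48% of those changed by 1, 96% at 2 and 98% at 3, with 7 false calls. Alternatives covered the replicate numbers, the tag 037, normalization, filter, probe set choice, variance model, set test and the removal of each sample. Probe sets with several genes or none were left out of the comparison and tested apart.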

Results

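The comparison asked how gene expression in lympho-myeloid multipotent progenitors differed between FLT3-ITD and wild type mice. There were 4 arrays per genotype, of which replicate 037 may repeat replicate 1, although these 2 were the least alike within each genotype (r = 0.969 in wild type, 0.953 in FLT3-ITD). With both averaged, 57 genes rose and 16 fell, against 46 and 19 in the comparison of all 8 arrays. Only 39 rises and 12 falls were shared between these. Pairwise correlations between arrays over probe sets ranged from 0.948 to 0.981. FLT3-ITD replicate 1 stood apart, with correlations of 0.948 to 0.959 to the other 7 arrays. FLT3-ITD replicate 037 had the highest difference between 3′ and 5′ Gapdh control probe sets, a sign of RNA quality, at 2.99 against 1.82 to 2.29 in the others. Its beta-actin difference was also the highest, at 0.17 against −0.48 to −0.32 in the others. The Gapdh difference averaged 1.94 ± 0.12 in wild type and 2.29 ± 0.50 in FLT3-ITD (SD, n = 4 each; exact permutation p = 0.2). For beta-actin the averages were −0.40 ± 0.06 and −0.27 ± 0.30 (exact permutation p = 0.657).

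Flt3 itself, the altered gene, was lower in FLT3-ITD. Its probe set read 10.54 ± 0.11 in wild type and 9.37 ± 0.39 in FLT3-ITD (log2, SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). The difference was −1.17 ± 0.20 (SE; limma adjusted p = 0.0406), and every FLT3-ITD value lay below every wild type value. A duplication within the coding region need not alter the probe target, so this level does not check the labels. The limma call was lost on leaving out any of 7 samples, FLT3-ITD replicate 1 being the exception, with adjusted p up to 0.154.

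Of the genes for the markers in the gate, Cd48 rose by 1.06 ± 0.13 (limma adjusted p = 0.00740), and Kit read −0.47 ± 0.17 relative to wild type (limma adjusted p = 0.427), short of the threshold. Ly6a, which encodes Sca-1, was not analysed here, and Slamf1, which encodes CD150, did not pass the filter on dim probe sets. Outside the gate, the progenitor marker Cd34 read −0.08 ± 0.12 and Ptprc, which encodes CD45, 0.00 ± 0.16, neither past the test.

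Across 10763 tested genes, 65 passed, 46 higher and 19 lower in FLT3-ITD. Of these, 43 rises and 15 falls reached a fold of 2. In all 65 the values of the genotypes did not overlap; over all tested genes that held for 6.22%, against 2.86% by chance. At an unadjusted p under 0.05 there were 618 higher and 413 lower genes, against 269 expected by chance in each direction. Leaving out single samples left 28 to 45 rises and 2 to 14 falls. The falls numbered 2 without wild type replicate 2, 2 without wild type replicate 3 and 4 without FLT3-ITD replicate 2. Of 30 named genes past the test besides Flt3, 16 lost the call on leaving out at least 1 sample, among them the rises of Tlr3, Plbd1, Ccr2 and Ifitm1 and every named fall except Hbb-b2.

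Socs2, a feedback inhibitor of cytokine signalling induced by STAT5, had the largest change, with each gene read from its probe set of highest mean. It went from 4.52 ± 0.59 to 11.07 ± 0.15 (log2, SD, n = 4 each), a difference of 6.55 ± 0.27 or 93.6-fold (limma adjusted p = 1.9e-05). Its other 5 probe sets were also higher, by 1.08 to 5.38, and the mean over its probe sets by 3.43 ± 0.20. On that measure Cd74 at 4.12, H2-Eb1 at 4.02 and H2-Aa at 3.57 differed more than Socs2. As means over their probe sets Id2 differed by 2.15 and Naaa by 1.71, both still past the test. Other large rises were Tlr3, a receptor for double-stranded RNA, by 4.36 ± 0.57, Id2, an inhibitor of E-protein transcription factors, by 3.76 ± 0.28, the chemokine receptor gene Ccr2 by 3.62 ± 0.52, Naaa, a lysosomal amidase, by 3.39 ± 0.33, Plbd1 by 3.17 ± 0.45, Clec1a by 3.12 ± 0.27 and Rnd3 by 3.06 ± 0.34. In wild type, Socs2, Tlr3, Id2, Ccr2, Naaa, Clec1a and Rnd3 averaged 4.52 to 5.34, below the array medians of 5.98 to 6.05. They passed the filter mainly through the FLT3-ITD arrays, so these rises start from dim values. The other probe set of Tlr3, at a mean of 3.82, was higher by 1.53. As a mean over its probe sets Tlr3 did not pass the filter and was not tested. The probe sets of Socs2, Tlr3, H2-Aa, H2-Ab1, Wfdc18 and Erdr1 are of types open to cross-hybridisation or shared transcripts.

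**Figure D1:**
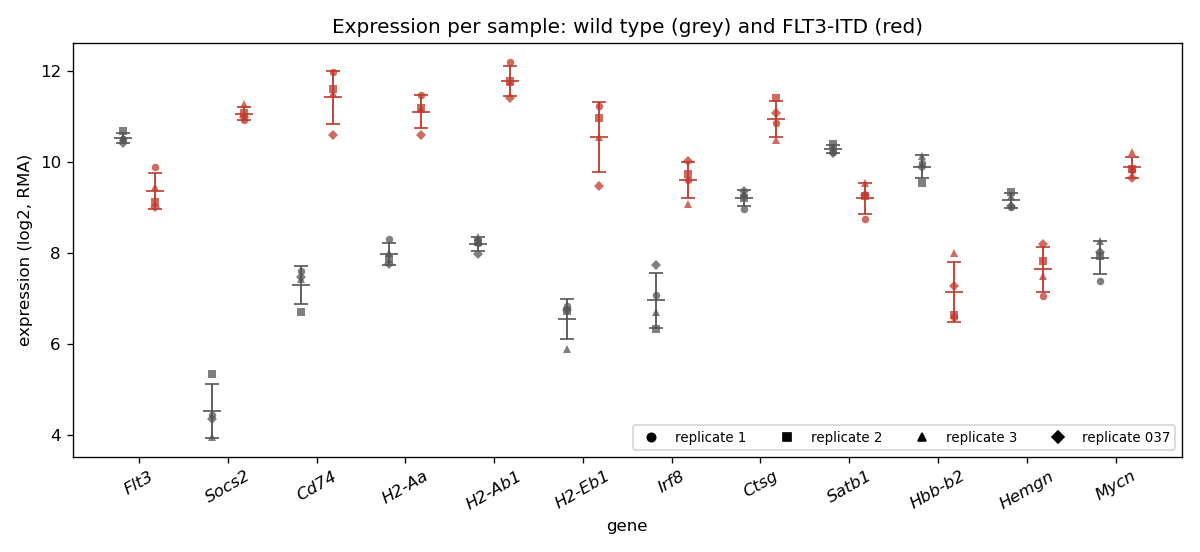
Expression (log2) of 12 genes in each of the 8 samples, wild type in grey and FLT3-ITD in red; symbols mark replicates, and bars give the mean ± SD of 4 samples. Each gene is read from its probe set of highest mean. The genotypes do not overlap for any gene shown, and on these probe sets Socs2 differs most, by 6.55.

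Among 17 tested STAT5 targets, 13 had a positive difference and 1, Socs2, passed over all genes; 2 rose when adjusted over the list alone. The list was higher by camera (adjusted p = 0.00165), with adjusted p = 0.101 with an estimated correlation, and higher by fry (adjusted p = 0.000452). With its member of smallest p left out, an alternative chosen after seeing the data, camera gave adjusted p = 0.0369. Cish, another STAT5 target, read 1.19 ± 0.29 higher and did not pass (limma adjusted p = 0.163). Dendritic cell markers were higher by camera in the same samples (mean 1.52; adjusted p = 0.215 with an estimated correlation).

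Several genes of antigen presentation by MHC class II rose. Cd74, the invariant chain, rose by 4.12 ± 0.31, H2-Eb1 by 4.02 ± 0.38, H2-Ab1 by 3.58 ± 0.18 and H2-Aa by 3.13 ± 0.21 (limma adjusted p from 5.4e-05 to 0.00279). Irf8, a transcription factor of monocyte and dendritic cell development, rose by 2.64 ± 0.31. These are members of the dendritic cell marker list, in which 13 genes were tested: 5 rose, 1, Flt3, fell, and adjusted over the list alone 7 rose and 1 fell. The list was higher by camera (adjusted p = 1.1e-06), with adjusted p = 0.215 with an estimated correlation and 0.0891 on ranks, an alternative chosen after seeing the data. Other genes of this pathway did not pass: Ciita, the regulator of MHC class II genes, read 1.27 ± 0.32 higher (limma adjusted p = 0.183), H2-Oa 0.90 ± 0.33 (limma adjusted p = 0.420) and H2-DMa 0.43 ± 0.22 (limma adjusted p = 0.602). B cells and macrophages also carry MHC class II. B cell markers had a median difference of 0.01 over 6 tested genes (camera adjusted p = 0.712), with none past the test over all genes and 1 higher when adjusted over the list alone. Of these, Fcrla read 0.66 ± 0.20 (limma adjusted p = 0.282). Monocyte-macrophage markers had a median difference of 0.26 and a mean of 0.83 over 5 tested genes (fry adjusted p = 0.0121; camera adjusted p = 0.238); the 4 besides Ccr2 averaged 0.13.

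Granulocyte-monocyte progenitor genes were higher in FLT3-ITD, with positive differences in 21 of 23 tested. Past the test were Ccr2, Irf8 and Ctsg, which encodes the granule protease cathepsin G and rose by 1.74 ± 0.20 (limma adjusted p = 0.00734); 6 rose when adjusted over the list alone. The camera adjusted p was 7.9e-09, with adjusted p = 0.215 with an estimated correlation; by fry it was 0.0264. Markers of mature neutrophils had a median difference of −1.19 over 8 tested genes (adjusted p = 0.473 with an estimated correlation, 0.309 by fry), and 1 of 5 monocyte-macrophage markers, Ccr2, rose. Adjusted over that list alone 1 rose and 1 fell.

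Early lymphoid genes were lower in FLT3-ITD in 13 of 18 tested, with a mean difference of −0.44. Satb1, a chromatin organiser of lymphoid development, fell by 1.08 on the log2 scale (SE 0.18; limma adjusted p = 0.0350), and its other 4 probe sets were lower too. That call was lost on leaving out any of 6 samples, FLT3-ITD replicates 1 and 3 being the exceptions, with adjusted p up to 0.142. No other member passed over all genes, and 6 were lower when adjusted over the list alone. This was the single list whose camera call (adjusted p = 3.0e-07) held with an estimated correlation, with adjusted p = 0.0225; fry gave 0.000393. Each FLT3-ITD sample lay below each wild type sample in the mean over the list, at −0.48 to −0.39 against −0.06 to 0.09. Among the lists past camera, the genotypes also separated fully for dendritic cell, granulocyte-monocyte progenitor, STAT5 target, ERK output and erythroid genes. Such list means can rest on few members. The mean difference was −0.98 and the median −0.07 for erythroid markers, and 0.59 and 0.29 for STAT5 targets. Without the filter on dim probe sets, Il7r, which encodes the interleukin-7 receptor, was lower by −2.49 ± 0.35 (limma adjusted p = 0.0309). Dntt, which encodes terminal transferase, read −0.87 ± 0.16 (limma adjusted p = 0.0696), short of the threshold. B cell markers did not pass camera (adjusted p = 0.712).

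The stem cell list was lower by camera (adjusted p = 0.00713), with adjusted p = 0.401 with an estimated correlation and 0.495 by fry. Of 17 tested genes, 14 had a negative difference, yet both members past the test rose: Clec1a, and the transcription factor gene Mycn by 1.98 ± 0.21 (limma adjusted p = 0.00385). As the mean over its 3 probe sets, Mycn differed by 1.08 ± 0.40 and did not pass (limma adjusted p = 0.380). Adjusted over the list alone, 2 rose and 6 fell. Without FLT3-ITD replicate 2 the camera adjusted p was 0.0507.

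ERK pathway output, which includes negative feedback genes, was lower by camera (adjusted p = 0.00713; adjusted p = 0.215 with an estimated correlation, 0.0863 by fry). None of its 16 tested genes passed by limma over all genes, 1 was lower when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Dusp6, an ERK phosphatase, read −1.64 ± 0.34 (limma adjusted p = 0.103) and Spry2 −0.92 ± 0.32. Without FLT3-ITD replicate 037, whose Gapdh difference was highest, the camera adjusted p was 0.109. Immediate early and stress genes were lower by camera (adjusted p = 0.0176; adjusted p = 0.583 with an estimated correlation), with a median of −0.18 and a mean of −0.02 over 17 genes. None passed by limma, 1 was lower at an unadjusted p under 0.05 and 1 when adjusted over the list alone, and that call ended without wild type replicate 2 (0.143), wild type replicate 3 (0.177) or FLT3-ITD replicate 037 (0.423). Nr4a1 read −1.04 ± 0.25 and Hspa1a 1.90 ± 0.93, neither past the test.

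The haemoglobin gene Hbb-b2 fell by 2.76 on the log2 scale (SE 0.31; limma adjusted p = 0.00576), Slc4a1, the red cell anion exchanger, fell by 2.10 (SE 0.34), Hemgn fell by 1.52 (SE 0.24) and Car2, a carbonic anhydrase, fell by 1.01 (SE 0.17). Of 5 tested erythroid markers, Hbb-b2 and Slc4a1 passed, also when adjusted over the list alone; the mean was −0.98 and the median −0.07. The list's camera adjusted p of 0.00475 became 0.170 without its member of smallest p, likewise chosen afterwards, with adjusted p = 0.232 with an estimated correlation. The megakaryocyte-erythroid list did not pass (camera adjusted p = 0.411), with Car2 its 1 called member over all genes and over the list alone.

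Mature neutrophil markers were lower by camera (adjusted p = 0.00165; adjusted p = 0.473 with an estimated correlation, 0.309 by fry). No single member of the 8 passed by limma, over all genes or adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Ngp read −2.39 ± 0.67 (limma adjusted p = 0.255) and Ltf −0.77 ± 0.31. The other largest falls were Erdr1 at −2.27 ± 0.38, the secreted proteins Wfdc18 at −2.08 ± 0.29 and Wfdc17 at −1.64 ± 0.24, Slc35d3 at −1.82 ± 0.30, Gcnt2 at −1.68 ± 0.28, the nuclear receptor gene Rora at −1.60 ± 0.26, syndecan-1 (Sdc1) at −1.58 ± 0.25 and Dach1 at −1.30 ± 0.19. As means over their probe sets Erdr1 (limma adjusted p = 0.0875), Sdc1 (0.0984) and Dach1 (0.0687) did not pass, and Hbb-b2 differed by −1.45 and passed. A single other probe set of Erdr1 differed by 0.01, and 3 of the other 8 of Rora had differences of the opposite sign. As a mean over its probe sets Rora did not pass the filter and was not tested.

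**Figure D2:**
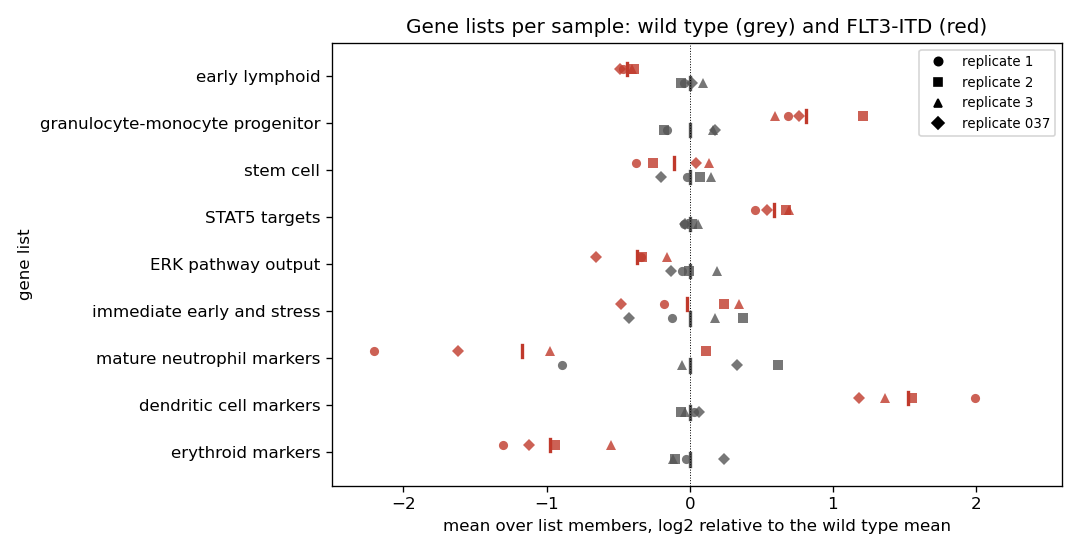
Mean over the tested members of each of the 9 gene lists past the camera threshold, as a log2 difference from the wild type mean, for each sample (wild type grey, FLT3-ITD red; symbols mark replicates, vertical bars genotype means). The genotypes separate fully for the early lymphoid list, with FLT3-ITD at −0.48 to −0.39. They also do so for the dendritic cell, granulocyte-monocyte progenitor, STAT5 target, ERK output and erythroid lists, where a mean can rest on few members. They overlap for the stem cell, mature neutrophil and immediate early lists.

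The remaining lists did not pass camera in the main comparison. The lists of cell cycle inhibitors, blood transcription factors, sorting markers, mast cells and basophils, and megakaryocyte-erythroid genes each passed under 1 alternative. Proliferation genes had 14 positive and 17 negative differences (adjusted p = 0.526), with Plk1 at 0.53 ± 0.18 and Tpx2 at −0.41 ± 0.17. Adjusted p was 0.234 for cell cycle inhibitors and tumour suppressors, 0.446 for p53 targets, 0.840 for the BCL2 family, 0.411 for glycolysis, 0.831 for ribosome biogenesis, 0.373 for sterol synthesis and 0.411 for the sorting markers. The interferon response list gave 0.643, although Ifitm1 rose by 1.58 ± 0.24 (limma adjusted p = 0.0248, and up to 0.104 on leaving out a sample). Blood transcription factors gave 0.201, with Id2 and Irf8 risen. Of the 35 tested, 21 had a negative difference, and adjusted over the list alone 2 rose and 2 fell. Marker lists of mast cells and basophils gave 0.286 and of endothelial and stromal cells 0.539. T and NK cell, megakaryocyte and eosinophil markers had 4, 4 and 0 tested members and were not tested as lists.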

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

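The tests of amplification evenness and of other splits of the samples were set before their results were seen; the tests of B cells, monocytes or macrophages, both kinds of dendritic cells, red cell and neutrophil RNA, erythroid-primed progenitors, 3′ bias and a wrong genotype were chosen after seeing the result or some of its genes. The test of monocytes or macrophages was run in 3 forms. Its first 2 forms gave −0.13 (−0.35 to 0.08) over 12 markers without the called Ccr2, and −0.28 (−0.55 to −0.01) over 9 macrophage genes picked after their values were seen, both below the bound of 0.5. They were dropped because lists made that way exclude nothing, and the third form, on the full list, came with an added rule that a called member keeps the explanation open.

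In 186 groups of 4 values, 9 had a sample far from the other 3; chance gives about 1 in 20 groups. The first principal component placed FLT3-ITD replicate 1 at 52.0, with the other FLT3-ITD samples at 2.76 to 4.80. Wild type replicate 3 was lowest for H2-Eb1 at 5.88, and FLT3-ITD replicate 2 was lowest for Car2 at 9.76 and Kit at 8.77. Wild type replicate 037 was highest for Sparc at 7.15 and lowest for Nr4a1 at 7.92. FLT3-ITD replicate 037 was lowest for Cdkn1b at 8.76 and highest for Bcl2 at 12.59. Wild type replicate 1 was lowest for endothelial and stromal markers at −0.21. Among 3727 probe sets with several genes or none, which the comparison left out, 5 were higher and 11 lower in FLT3-ITD. They included 3 probe sets of the alpha globin genes Hba-a1 and Hba-a2 at −1.97, −2.99 and −4.44, and a probe set of several beta globin genes at −3.21.

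Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave as many as 65 genes, and the highest of the others gave 1. With the 8 samples counted as separate, that is the smallest share such a count can give, and it does not exclude chance. The other splits mix the genotypes, so a difference between genotypes would widen their spread and lower their counts. If samples 1 and 037 were repeats, the splits would be too few to say. For gene lists, 2 of the 35 splits gave 9 lists past camera. These were the real one and the split of wild type replicate 1 with FLT3-ITD replicates 1, 2 and 037 against the rest. The highest of the others was therefore 9, and chance cannot be excluded. Among the other splits 23 gave at least 1 list past camera, and their median was 2 lists.

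Several MHC class II and dendritic cell genes rose in FLT3-ITD, and B cells could have brought them. Against this, 13 B cell genes differed by −0.082 on average (95% interval −0.20 to 0.04), 5 of them upward. Cd79a read 5.29 in wild type and 5.09 in FLT3-ITD, Cd79b 6.86 and 6.92, and Cd22 4.46 and 4.77. Ighm, at 9.19 and 8.70, and Ly6d are also early lymphoid genes, a list that was lower. The fall of Ighm therefore does not speak against B cells. For plasmacytoid dendritic cells, 12 genes showed no rise as a set, at −0.11 (−0.32 to 0.10). Of them 4 were positive, with Bst2 at 0.51, and Siglech read 6.22 in wild type and 6.20 in FLT3-ITD. The 12 do not include the called Irf8, and Ccr9 and Ly6d among them are also early lymphoid genes. The list therefore does not exclude plasmacytoid dendritic cells. For the conventional dendritic lineage, 17 genes outside the called and MHC class II genes averaged 0.68 (0.33 to 1.03), which neither cleared nor excluded the bound of 0.5 set for it. Of the 17, 14 had a positive difference. Zbtb46 read 5.67 in wild type and 8.05 in FLT3-ITD and Xcr1 4.65 and 6.51, while Sirpa read 8.82 and 8.34. Conventional dendritic cells in a gate that excludes lineage-positive cells, and progenitors that express these genes themselves, cannot be told apart here. Monocytes or macrophages stay open too: their 13 markers averaged 0.15 (−0.08 to 0.38), but Ccr2 rose and Csf1r read 7.56 in wild type and 8.52 in FLT3-ITD, while C1qa read 6.06 and 5.63.

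Some erythroid genes fell in FLT3-ITD, while 13 abundant neutrophil genes averaged −0.91 with a 95% interval that spans 0 (−2.04 to 0.23). The 13 include Wfdc17, which passed the test at −1.64 (limma adjusted p = 0.0248). Red cell RNA in the wild type samples may contribute to the falls: abundant red cell genes averaged −0.64 over 17, but −0.27 (95% interval −0.43 to −0.11) over the 13 outside the called genes, which leaves it open. These lists leave out probe sets shared by several globin genes, which fell by −1.97 to −4.44 for alpha globin. A beta globin probe set went from 12.11 to 8.90, a difference of −3.21. They were called themselves and so are part of the pattern, which does not settle the question. Abundant neutrophil genes moved together between samples of one genotype, with a mean correlation of 0.621 over 10 genes against at most 0.311 in random lists matched on level. Neutrophil RNA in varying amounts would give this. The random lists were matched on level only, so the test cannot tell it from a shared program that varies in the progenitors themselves. Fewer erythroid-primed progenitors stay open, with 10 erythroid regulators at −0.075 (−0.31 to 0.16), several of them dim. FLT3-ITD itself stays an open biological explanation, and the gate excluded lineage-positive cells.

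FLT3-ITD replicate 1 stood apart from the other arrays. A sample of the other genotype is argued against by 81.4% of 59 genes called without it lying nearer the other FLT3-ITD samples. Uneven amplification of scarce transcripts was looked for as a larger excess spread of this sample at low expression. Among the 10763 tested genes the excess was nearly the same at low as at high expression (ratio 0.989). The filter had already removed dim probe sets, so the test cannot speak to scarcer transcripts. Stronger 3′ bias could not be settled: its Gapdh difference of 2.29 was above all arrays except FLT3-ITD replicate 037 at 2.99, while its actin difference of −0.48 was the lowest of all. No biological explanation was tested.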

How the results depend on the processing

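No result that answers the comparison changed direction; of 294 such values under alternatives, 236 stayed on the same side of the threshold or within 1.5 times the count. Leaving out FLT3-ITD samples 1 and 037, camera on ranks, and camera without each list's member of smallest p were chosen after seeing the data. The causes were not tested, except that fewer samples were fitted where samples were left out. The 46 rises became 26 without both samples tagged 037, 8 with an equal-variance test without moderation and 26 without FLT3-ITD samples 1 and 037; the 19 falls became 5, 0 and 5, and 30 with array weights. The equal-variance test had 557 higher and 359 lower genes at an unadjusted p under 0.05. Leaving out 1 sample at a time gave 28 to 45 rises, fewest without wild type replicate 3, and 2 to 14 falls. The falls were 10, 2, 2 and 6 without wild type replicates 1, 2, 3 and 037, and 14, 4, 8 and 9 without FLT3-ITD replicates 1, 2, 3 and 037. 

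The limma call of Flt3 ended without both samples tagged 037 (−1.09, adjusted p = 0.168), with all probe sets tested (−1.17, adjusted p = 0.0533) and with the equal-variance test (−1.17, adjusted p = 0.196). Without 1 sample at a time its difference ranged from −1.34 to −1.05, with adjusted p from 0.00808 to 0.154.

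With an estimated correlation, adjusted p was 0.215 for dendritic cell markers, ERK output and granulocyte-monocyte progenitor genes, 0.232 for erythroid markers, 0.583 for immediate early genes, 0.473 for neutrophil markers, 0.101 for STAT5 targets and 0.401 for stem cell genes. By fry it was 0.0863 for ERK output, 0.495 for immediate early and for stem cell genes, and 0.309 for neutrophil markers. Without both samples tagged 037 it was 0.0726 for ERK output, 0.177 for erythroid markers, 0.254 for immediate early genes and 0.131 for neutrophil markers. Without FLT3-ITD samples 1 and 037 these were 0.117, 0.199, 0.712 and 0.370. Camera on ranks gave 0.0891 for dendritic cell and 0.213 for erythroid markers. Without the member of smallest p, erythroid markers gave 0.170 and immediate early genes 0.0680. Averaging samples 1 and 037 of each genotype, which share the number 1 and may be repeats, gave 57 rises and 16 falls, and 0.0688 for erythroid markers. Of these rises and falls, 39 and 12 were also called in the main comparison. Without 1 sample at a time, adjusted p ranged from 0.00264 to 0.109 for ERK output, 0.00297 to 0.423 for immediate early genes and 0.00194 to 0.0507 for stem cell genes.

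With the replicate number as a block there were 19 rises and 3 falls, and Flt3 differed by −1.17 with adjusted p = 0.119. The block changed no call of a gene list by camera. The samples were not treated as pairs: deviations of same-numbered samples correlated at 0.027, 0.037, 0.065 and 0.110 for numbers 1, 2, 3 and 037, so a single number exceeded 0.1, and those numbered 2 correlated better with another number, at 0.054. For the other 3 the same number gave the highest correlation, a hint from the data that the numbers share something, which was not tested. Immediate early genes were lowest in the samples tagged 037 of both genotypes, at −0.42 in wild type and −0.48 in FLT3-ITD. Of 30 named genes past the test besides Flt3, 14 passed without each sample in turn, and Cd74, H2-Aa, H2-Ab1, Id2 and Socs2 passed under every alternative run on them; none of 677 values changed direction.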

Other observations

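The lysosomal hypothesis was tested after some of its genes had been seen; all genes named here were chosen after their values were seen.

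Of the 65 called genes, 47 belonged to no list, 33 higher and 14 lower. No theme was tested over these genes. Mpeg1, which encodes a pore-forming protein of macrophages, rose by 3.04 ± 0.29, the cathepsin gene Ctsh by 2.58 ± 0.40, Ifi30, a lysosomal thiol reductase of antigen processing, by 1.62 ± 0.26, Cst3, a cathepsin inhibitor, by 1.54 ± 0.20 and the lysosomal activator protein gene Psap by 1.25 ± 0.19 (SE; limma adjusted p from 0.00279 to 0.0330). Other rises were S100a4 by 1.62 ± 0.15, Timp3 by 2.28 ± 0.22, Tnfsf11, which encodes RANK ligand, by 2.37 ± 0.27 and the chemokine receptor gene Cxcr3 by 1.60 ± 0.19. In wild type, Tnfsf11, Cxcr3, Ctsh and Timp3 averaged 4.54 to 5.49, below the array medians, so their rises start from dim values. Hmox1, which encodes haem oxygenase 1, fell by 1.17 on the log2 scale (SE 0.18; limma adjusted p = 0.0282) beside the haemoglobin transcripts.

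Lysosomal genes may be higher in FLT3-ITD beyond those already called. Of a list of lysosomal genes, 40 were tested and 6 had been called. Of the other 34, 22 had a positive difference, with a median of 0.23, and camera over the uncalled genes gave p = 0.000839, or p = 0.010 with an estimated correlation. Dendritic cell markers were higher by camera in the same samples, with adjusted p = 0.215 with an estimated correlation and 4 of 13 tested members negative. The lysosomal list does not say which cells held the transcripts.

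Without the filter on dim probe sets, Cpa3, a protease gene of mast cells and their progenitors, was lower by −1.10 ± 0.15 (limma adjusted p = 0.0308). A gamma T cell receptor gene, Trgv4, rose by 2.80 ± 0.47 (limma adjusted p = 0.0410), while the 4 tested T and NK cell markers had a median of 0.13.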
